A study of Mus musculus with 15 samples.

How the data were processed

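RNA was measured in the intestine of mouse embryos at E16.5 (the embryonic day), in 15 libraries that the labels divide into 3 genotypes of 5 libraries each. All 3 genotypes lacked Mlkl, and they carried wildtype Casp8, a Casp8 knockout or a Casp8 knockin with the C362A substitution. Per the labels' protocols, total RNA was purified on columns with DNase digestion, polyA libraries were made from 0.5 ug with a TruSeq v2 kit, and single-end reads of 50 bp were sequenced on a HiSeq4000. That kit does not mark the strand, so reads of a gene and of a gene overlapping it on the other strand cannot be told apart. The labels give no litter, sex, library batch or replicate number. Libraries were therefore numbered within a group in accession order, and the numbers pair nothing.

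Per the submitters' processing notes, the reads were aligned with GSNAP to GRCm38. The aligner version, its settings and the annotation used for counting are not given in the sources used here. Each file lists 36528 Entrez gene IDs. The deposited counts are uniquely aligned reads within a gene model, per the file headers. The deposited RPKM values were adjusted by a size factor for each library, per the file headers, and the method behind that factor is not given in the sources used here. Across 13798 genes compared between libraries, the RPKM values differed from the counts only by 1 factor per library and 1 length per gene, with a largest residual of 1.1e-14 on the log2 scale. Counting unique alignments lowers the counts of genes with near-identical copies, and a mutation that leaves the transcript intact cannot be seen in such counts.

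Gene names and coordinates were taken from RefSeq on GRCm38.p6 by Entrez ID for 31049 IDs and from GENCODE for 78 more. The remaining 5401 IDs stayed unnamed, held 1.68% to 1.95% of the counts of a library, and were kept in the tests. Total counts lay between 31896399 and 38532127 per library, and 22295 to 24039 genes had a count. H19 was the most abundant gene in every library, with 1.76% to 2.64% of counts. The 20 most abundant genes held 6.93% to 8.72% of counts, and mitochondrial genes 1.13% to 1.65%. Over genes with a mean count of at least 50, every pair of libraries within a genotype differed by a chi-square per gene of 10.69 to 138.21, far above sampling noise. Pairs across genotypes were not compared. Each library was counted as its own sample.

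The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, and robust empirical Bayes estimates. All 15 libraries entered 1 fit with a mean per genotype, 18370 genes were tested, and the biological coefficient of variation was 0.174. Adjusted p-values follow Benjamini and Hochberg over the genes tested, and genes under 0.05 were called changed. Log2 fold changes and standard errors (SE) come from that fit. Levels are counts per 1e6 counts (CPM) scaled by the TMM factors, given as mean ± SD over the 5 libraries of a group. Limits of precision from depth were small beside the spread between libraries for most genes, but genes under 1 CPM rest on few reads per library.

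Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over 31 lists per comparison. A further list of Y-linked genes and Xist was only described. Of 591 list entries, 582 were found by symbol and 2 by an older symbol, 4 were not found and 3 were repeats. Beside each list result stands the number of members past the gene test over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were run as alternatives.

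The groups, tests, gene lists, main alternatives and the rule for naming genes were fixed before the data were examined. The rule named Casp8, Mlkl, Cflar, Fadd, Ripk1 and Ripk3 throughout. In each comparison it added the called genes with the largest changes, up to 6 in each direction, with a mean log2 CPM of at least 1 and no overlap between the 5 and 5 libraries. It also took the 3 members with the smallest p in the lists for interferon-stimulated genes, inflammasome, NF-kB and enterocyte, whether or not they passed, and, from lists with at least 3 called members, the 3 called members with the smallest p. Where fewer than 5 genes were called, the 5 smallest p were named. All other genes named, including single members given as examples of lists, were chosen after their values were seen, also where the text does not repeat this.

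The alternatives fixed at that time were other scalings (RLE, library totals, the 20 most abundant genes left out), DESeq2 1.42.0, limma-voom, robust estimates off, no filter, a filter of 5 CPM in at least 5 libraries, fits of only the groups compared, a block for runs of consecutive sample ID numbers, covariates for Y-linked and erythroid expression, each library left out in turn, a stricter threshold of 0.01 and a minimum absolute log2 fold change of 1. Those added after seeing the data were covariates for the enterocyte list mean, for posterior Hox genes and for the mean of Muc6 and Tff2, camera with an estimated correlation in the fit with the enterocyte covariate, 2 surrogate variables (sva 3.50.0), limma on log2(RPKM + 1), and a fit without the 3 libraries in which gut region genes stood apart. Because the C362A and knockout groups share the wildtype libraries, their comparisons were set beside 30 simulated draws with unchanged groups and beside 20 fits with disjoint wildtype libraries.

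The steps were tested on simulated data with 200 changed genes. For C362A against wildtype (18227 genes), 53.7% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, with 10 false calls among 166. For knockout against wildtype (18215 genes) the shares were 55.2%, 70.1% and 95.5%, with 9 false calls among 161. For C362A against knockout (18211 genes) they were 47.8%, 83.6% and 92.4%, with 11 among 165. A list shifted 1.3-fold was called in all 3 simulated comparisons, beside 1, 0 and 0 of 30 unshifted lists. The simulated genes were drawn independently of each other, so this does not show how the list test or the number of false gene calls behaves with correlated genes. With 200 changed genes the adjusted threshold is also looser than with few, so the shares recovered may be lower in the data. In the data the estimated correlation was 0.787 for the proliferation, 0.699 for the enterocyte and 0.561 for the interferon list. Nothing in the labels says that each library of a group came from a separate embryo. Y-linked genes were expressed in some but not all libraries of each genotype, so no genotype rests on 1 embryo alone. The p-values measure the spread between these samples, which may be partly technical.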

Results

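Transcript levels were measured by RNA-seq in the intestine of mouse embryos at E16.5 (the embryonic day), in 3 genotypes with 5 libraries each. All samples were of an Mlkl knockout background, which removes the pseudokinase that carries out necroptosis. The genotypes differed in Casp8, which encodes caspase-8, the initiator protease of death-receptor apoptosis. One group kept wildtype Casp8 (wildtype), one had Casp8 knocked out (knockout), and one carried Casp8 with the C362A substitution, which replaces the catalytic cysteine with alanine (C362A). The labels mark the tissue of every C362A library as inflamed and that of all other libraries as normal. Whether this was found in each animal or given to the group as a whole is not known here. Libraries held 31896399 to 38532127 counts, and between 22295 and 24039 genes had a count in a library.

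Casp8 itself (Entrez 12370, chr1:58795233-58847503, GRCm38) was present at wildtype levels in the C362A libraries and was strongly reduced in the knockout libraries. Its level was 70.1 ± 5.97 CPM in wildtype (SD, n = 5, 2273 to 2605 counts per library), 69.9 ± 3.41 CPM in C362A (n = 5, 2286 to 2430 counts) and 14.4 ± 1.65 CPM in knockout (n = 5, 390 to 608 counts). All 5 knockout libraries lay below all 10 others. The log2 fold change was −2.28 (SE 0.08) for knockout against wildtype, with an adjusted p of 2.55e-11 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For C362A against wildtype it was 0.00 (SE 0.08, adjusted p = 0.987). Counts over the whole gene do not show the C362A substitution, and the remaining reads in the knockout were not assigned to exons here. Mlkl (Entrez 74568, chr8:111311255-111338479) was near the floor in all groups, at 0.389 ± 0.261 CPM in C362A, 0.521 ± 0.119 CPM in knockout and 0.506 ± 0.179 CPM in wildtype (n = 5 each).

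The partners of caspase-8 in cell death complexes did not differ detectably between the genotypes. Cflar, which encodes the catalytically inactive homolog cFLIP, was at 37.2 ± 4.05 CPM in C362A, 40.2 ± 3.21 CPM in knockout and 39.3 ± 1.74 CPM in wildtype. Fadd, the adaptor that recruits caspase-8, was at 37.2, 36.6 and 36.6 CPM in the same order. The kinase genes Ripk1 (59.9, 61.2 and 59.5 CPM) and Ripk3 (40.3, 40.2 and 41.7 CPM) were as close. No log2 fold change of these 4 genes lay outside −0.11 to 0.04 in any comparison, and none passed. The 20 measured genes of the death receptor and necroptosis list did not move as a group in C362A against wildtype (camera adjusted p = 0.362).

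**Figure D1:**
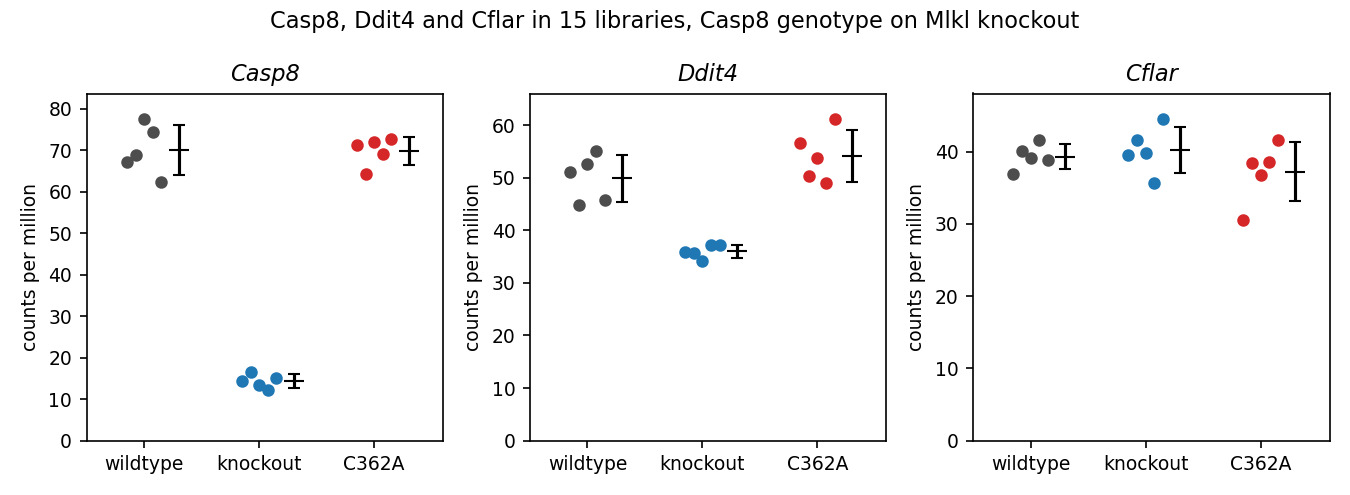
CPM (linear axes from 0) of Casp8, Ddit4 and Cflar in each of the 15 libraries (points), by genotype, with bars for mean ± SD (n = 5 per group). Casp8 averages 14.4 CPM in the knockout libraries, 69.9 CPM in C362A and 70.1 CPM in wildtype.

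The comparison of C362A with wildtype asks what the inactive enzyme does to the tissue when necroptosis through Mlkl is blocked. In C362A intestine 15 genes were higher. Cxcl10, an interferon-inducible chemokine, rose to 4.29 ± 0.751 CPM from 0.734 ± 0.125 CPM in wildtype (log2 fold change 2.54, SE 0.20, n = 5 each). Mmp9, a gelatinase abundant in neutrophils, was at 37.0 ± 6.82 against 15.8 ± 3.50 CPM (1.23, SE 0.16). Adgre1, which encodes the macrophage surface protein F4/80, was at 14.3 ± 1.42 against 8.52 ± 0.853 CPM (0.75, SE 0.13). Il2rg, the common gamma chain of lymphoid cytokine receptors, was at 11.5 ± 1.10 against 6.80 ± 1.10 CPM (0.75, SE 0.13).

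In total 15 of 18370 genes were higher and 0 were lower in C362A than in wildtype by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 1485 were higher and 1432 lower. DESeq2 called 47 higher and 7 lower, limma-voom 14 and 0, and limma on log2(RPKM + 1) 16 and 0. The adjusted p-values were 7.96e-06 for Cxcl10 (chr5:92346638-92348889), 0.00201 for Mmp9 (chr2:164940326-164955850), 0.0201 for Il2rg and 0.0361 for Adgre1 in that edgeR test. Also named by the fixed rule were Clec4n, the gene of the C-type lectin Dectin-2 (1.06, SE 0.14, adjusted p = 0.00201 by edgeR), Dnase1l3, a secreted DNase made by macrophages and dendritic cells (1.3, SE 0.21), and Serpina3g, a serine protease inhibitor gene (1.5, SE 0.24), the last 2 at an adjusted p of 0.0145 by edgeR.

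The other called genes were chosen after their values were seen. They were Slamf8 (2.18, SE 0.23, chr1:172581377-172590873), a SLAM family receptor gene of myeloid cells, Mgl2 (1.87, SE 0.21), a macrophage lectin gene, and Spic (2.01, SE 0.26), a transcription factor gene of red pulp macrophages. Beside these stood Serpina3f (2.24, SE 0.31), the chemokine gene Ccl12 (1.65, SE 0.26), Apobec3 (0.56, SE 0.09), which encodes a cytidine deaminase, and Madcam1 (0.64, SE 0.12), an endothelial ligand for homing lymphocytes. Their edgeR adjusted p-values ran from 0.000295 for Slamf8 to 0.0431 for Madcam1. The gene with ID 102641905 had the same counts as Ccl12 in every library, so the 15 calls are 14 separate signals. Serpina3f and Serpina3g belong to a cluster of near-identical copies, so their reads may be split among them. Each of the 15 was higher in 5 of 5 C362A libraries than in every wildtype library. Chance gives this separation to 0.397% of unselected genes. The 15 were called from these same libraries, and the naming rule required no overlap of some, so the separation adds no support.

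**Figure D2:**
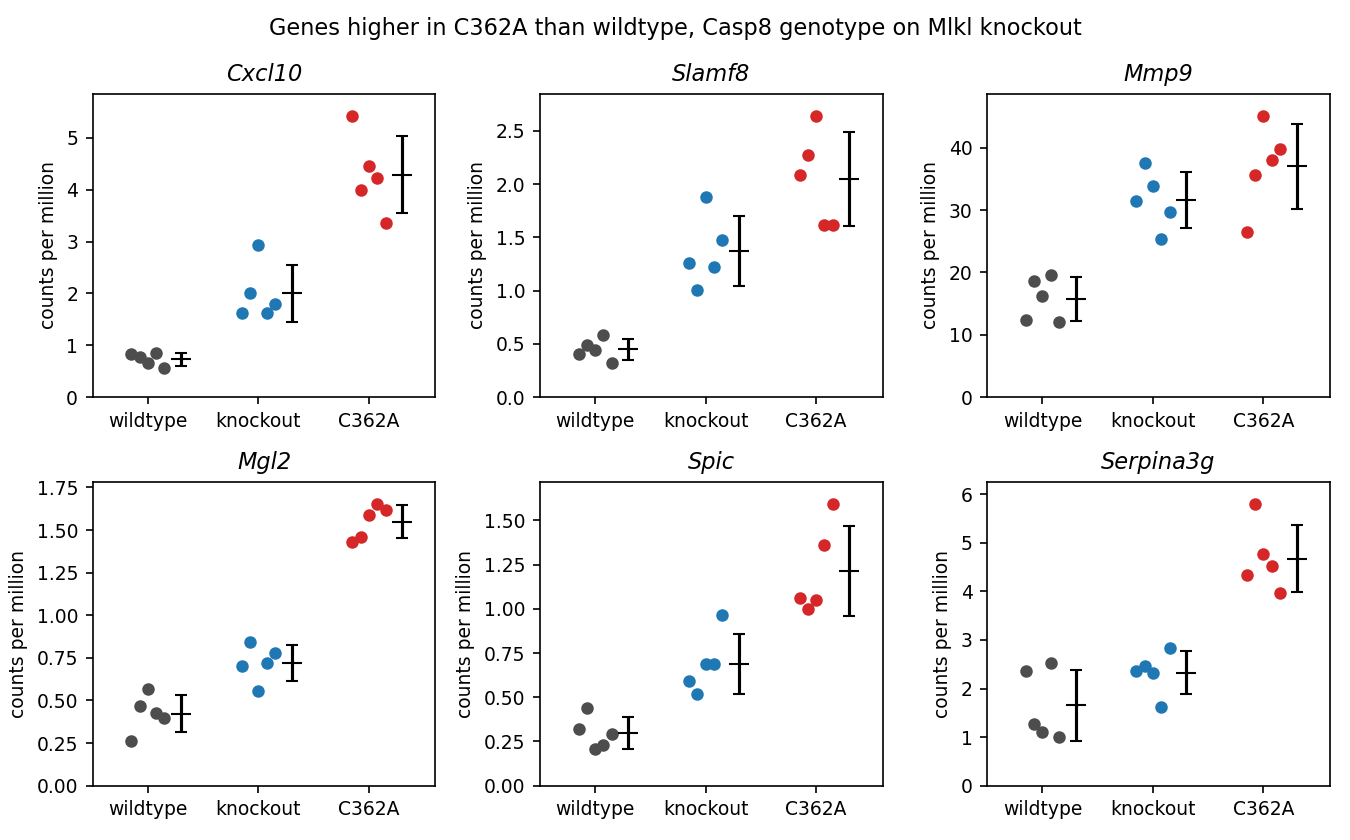
CPM (linear axes from 0) of Cxcl10, Slamf8, Mmp9, Mgl2, Spic and Serpina3g in each of the 15 libraries (points), by genotype, with bars for mean ± SD (n = 5 per group). Cxcl10 averages 4.29 CPM in C362A, 2 CPM in knockout and 0.734 CPM in wildtype.

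How many genes were called depended on single libraries. Without C362A replicate 5 the count was 1807 (794 higher, 1013 lower), and those contained all 15. It was 7 without C362A replicate 2, C362A replicate 3 or wildtype replicate 5, and 10 without wildtype replicates 2 or 4. Cxcl10, Slamf8, Mgl2, Spic, Mmp9, Clec4n and Serpina3f passed whichever library was left out. Most of these were near the floor in wildtype. Cxcl10, Slamf8, Mgl2, Spic and Serpina3f averaged 0.734, 0.451, 0.423, 0.297 and 0.187 CPM there, on 3 to 29 counts per library. The size of their fold changes therefore rests on few reads. The other calls were lost without some libraries, and the most sensitive were Madcam1, which passed only without C362A replicates 1 or 5 or wildtype replicate 3 (edgeR adjusted p up to 0.17), and Adgre1, which passed only without C362A replicate 5 or knockout replicates 3, 4 or 5 (up to 0.174). Apobec3 was lost without C362A replicates 1 to 4 or wildtype replicates 1, 2, 3 or 5 (up to 0.12), and Il2rg without C362A replicates 2, 3 or 4 or wildtype replicates 2, 4 or 5 (up to 0.0985). Serpina3g was lost without C362A replicates 2 or 3 or wildtype replicates 2, 3 or 5 (up to 0.083), Ccl12 without C362A replicates 2 or 3 or wildtype replicates 4 or 5, and Dnase1l3 without C362A replicates 2 or 3 or wildtype replicate 5 (both up to 0.0704), all by edgeR. A filter of at least 5 CPM in 5 libraries left 1 call, and the covariate for Y-linked expression left 7. Y-linked genes were expressed in 2 of 5 C362A, 4 of 5 knockout and 4 of 5 wildtype libraries.

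By camera, 13 of 31 gene lists passed in C362A against wildtype, 11 higher and 2 lower. With an estimated correlation between genes 0 of the 13 passed, at adjusted p = 0.632 for each but NF-kB (adjusted p = 0.262) and the inflammasome list (adjusted p = 0.684). By fry, 1 list passed, NF-kB (adjusted p = 0.0029).

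The NF-kB, interferon and GTPase lists were higher in C362A, while MHC class I (median −0.01, 8 of 16 positive, camera adjusted p = 0.362) and the antimicrobial list (camera adjusted p = 0.474) did not pass. The NF-kB and cytokine response list had a median log2 fold change of 0.21, with 19 of 25 members positive (camera adjusted p = 0.000182, and adjusted p = 0.262 with an estimated correlation). Cxcl10 was its 1 called member over all genes, while 9 higher and 1 lower (Lif, −0.71) passed adjusted over the list alone (5 higher and 2 lower over all genes without C362A replicate 5). Vcam1, an adhesion molecule of activated endothelium, was at 27.8 ± 5.54 against 15.6 ± 2.10 CPM (0.83, SE 0.16, edgeR adjusted p = 0.0583), and Nfkbia, the gene of the NF-kB inhibitor, had 0.41 (SE 0.09, edgeR adjusted p = 0.2). Both passed without C362A replicate 5 (adjusted p = 0.0138 and 0.0274 in edgeR), while the fits without 1 library gave 0.0138 to 0.241 for Vcam1 and 0.0274 to 0.515 for Nfkbia. Interferon-stimulated genes had a median of 0.34 and 26 of 31 positive (camera adjusted p = 0.000182, and adjusted p = 0.632 with an estimated correlation). No single member passed in edgeR, 0 adjusted over the list alone, 8 higher and 0 lower at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom. The smallest p belonged to Ifit2 (0.38), Ifit3b (1.69, SE 0.50) and Bst2 (0.42), each with an edgeR adjusted p of 0.285. Without C362A replicate 5 the interferon list did not pass (camera adjusted p = 0.102), with 1 member past the test over all genes. Guanylate-binding and immunity-related GTPases had a median of 0.34 (camera adjusted p = 0.00209, and adjusted p = 0.632 with an estimated correlation). Of their 15 members 3 passed adjusted over the list alone, namely Irgm1 (0.42), Igtp (0.49) and Iigp1 (0.89), and 0 over all genes in edgeR (5 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom). That list did not pass without C362A replicate 5 (camera adjusted p = 0.0642), where 2 members were higher over all genes, and 3 higher and 2 lower adjusted over the list alone.

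Macrophage, neutrophil and mast cell markers were also higher. The macrophage and monocyte list had a median of 0.16 with 19 of 22 positive (camera adjusted p = 0.00249, and adjusted p = 0.632 with an estimated correlation). Adgre1 was its 1 called member. Adjusted over the list alone 3 were higher, Adgre1, the lysozyme gene Lyz2 (1) and the Fc receptor chain gene Fcer1g (0.35), and 1 was lower, the scavenger receptor gene Cd163 (−1.28). The neutrophil list had a median of 0.96 with 14 of 15 positive (camera adjusted p = 0.00249, and adjusted p = 0.632 with an estimated correlation). Mmp9 was its 1 member called over all genes and its 1 adjusted over the list alone, and the collagenase gene Mmp8 (2.04, SE 0.72) and Retnlg (1.74, SE 0.61) did not pass. This list did not pass without wildtype replicate 1 (camera adjusted p = 0.0654). All 9 mast cell and basophil genes were positive, with a median of 0.74 (camera adjusted p = 0.0113, and adjusted p = 0.632 with an estimated correlation; 0.0523 by camera without C362A replicate 3). The mast cell protease gene Mcpt4 (1.72, SE 0.45) was the 1 member that passed adjusted over the list alone, and 0 passed over all genes in edgeR (3 higher at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom). The T, NK and innate lymphoid list, which holds Il2rg, did not pass (camera adjusted p = 0.245). Leaving out C362A replicate 5, 3 macrophage, 3 neutrophil and 1 mast cell genes were higher and 1 macrophage gene was lower over all genes.

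Enterocyte genes were lower in C362A and cell cycle genes were higher. Of 25 enterocyte genes 24 were negative, with a median of −0.57 (camera adjusted p = 1.04e-07, and adjusted p = 0.632 with an estimated correlation). The brush border and lipid handling genes with the smallest p were Rbp2, a retinol-binding protein gene (462 ± 148 against 930 ± 579 CPM, −1.01, SE 0.35), Mep1a, a meprin protease gene (−0.38, SE 0.13), and Dgat1, a triglyceride synthesis enzyme gene (−0.55, SE 0.20), each with an edgeR adjusted p of 0.285. None of the 25 passed in edgeR, 0 adjusted over the list alone, 0 by DESeq2 or limma-voom, and 14 were lower at an unadjusted p under 0.05. Without C362A replicate 5, 7 passed over all genes and 18 adjusted over the list alone. Within the runs of consecutive sample ID numbers, the list mean differed between C362A and wildtype by −0.13 in a run with 2 libraries per group and by −0.76 in a run with 3 per group. All 22 proliferation genes were positive, with a median of 0.26 (camera adjusted p = 6.89e-06, and adjusted p = 0.632 with an estimated correlation). Top2a, a DNA topoisomerase gene, had 0.36 (SE 0.12), and the mitotic checkpoint kinase gene Bub1 had 0.33 (SE 0.12), both chosen after their values were seen. None of the 22 passed in edgeR, 0 adjusted over the list alone, 0 by DESeq2 or limma-voom, and 10 were higher at an unadjusted p under 0.05, while without C362A replicate 5, 11 passed over all genes and 16 adjusted over the list alone. With the enterocyte list mean as a covariate, an alternative chosen after seeing the data, the proliferation list had a median of −0.01 with 8 of 22 positive and did not pass (camera adjusted p = 0.419, in a range of 4.49e-07 to 0.875 over the alternatives).

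The lists of the gut wall were higher by small amounts, each with adjusted p = 0.632 with an estimated correlation. Fibroblast and matrix genes had a median of 0.22 (camera adjusted p = 2.48e-05, 18 of 20 positive), and smooth muscle genes 0.22 (4.08e-05, 14 of 14). Adjusted over the list alone 8 fibroblast genes passed, such as Col6a1 (0.24) and Foxf1 (0.25), and 4 smooth muscle genes, such as Cald1 (0.42) and Myh11 (0.26). Over all genes 0 of these passed in edgeR, DESeq2 or limma-voom, with 10 fibroblast and 7 smooth muscle genes higher at an unadjusted p under 0.05. The endothelium list had 0.13 (camera adjusted p = 0.0065, but 0.137 without wildtype replicate 5), with 1 member adjusted over the list alone, Pecam1 (0.27). Over all genes 6 fibroblast, 5 smooth muscle and 3 endothelium genes passed without C362A replicate 5, and 12, 10 and 4 adjusted over the list alone. The stem and progenitor list had 0.11 (camera adjusted p = 0.0417). It did not pass without C362A replicates 1, 2, 4 or 5 or wildtype replicates 2, 4 or 5 (camera adjusted p up to 0.179).

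Inflammasome and pyroptosis genes were lower in C362A, with a median of −0.24 and 15 of 20 negative (camera adjusted p = 0.0417, and adjusted p = 0.684 with an estimated correlation). Naip5, a cytosolic flagellin sensor gene (−0.64, SE 0.26, edgeR adjusted p = 0.291), Gsdme, a gasdermin gene (−0.24, 0.305), and Nek7 (0.16, 0.311) had the smallest p. None passed in edgeR, 0 adjusted over the list alone and 0 by DESeq2 or limma-voom, with 1 higher and 4 lower at an unadjusted p under 0.05. In the fit without C362A replicate 5, 2 were lower over all genes, among them Naip5 (edgeR adjusted p = 0.0237, with 0.0237 to 0.658 over the fits without 1 library), and 7 were lower and 1 higher adjusted over the list alone. The list did not pass without C362A replicates 1 or 2, wildtype replicates 2, 3 or 4, or knockout replicate 4 (camera adjusted p up to 0.172). With the enterocyte list mean as a covariate, chosen after seeing the data, the median of this list was 0.05. In 6 lists that did not pass, camera, median and mean were not of 1 sign. Higher by camera were MHC class I (median −0.01, mean 0.06) and, with medians of 0.09, 0.06 and 0.01 and means of −0.02, −0.01 and −0.03, the enteroendocrine, antimicrobial and hepatocyte lists. Lower by camera were the p53 list (median −0.04, mean 0.02) and the pancreas list (0.04 for both).

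**Figure D3:**
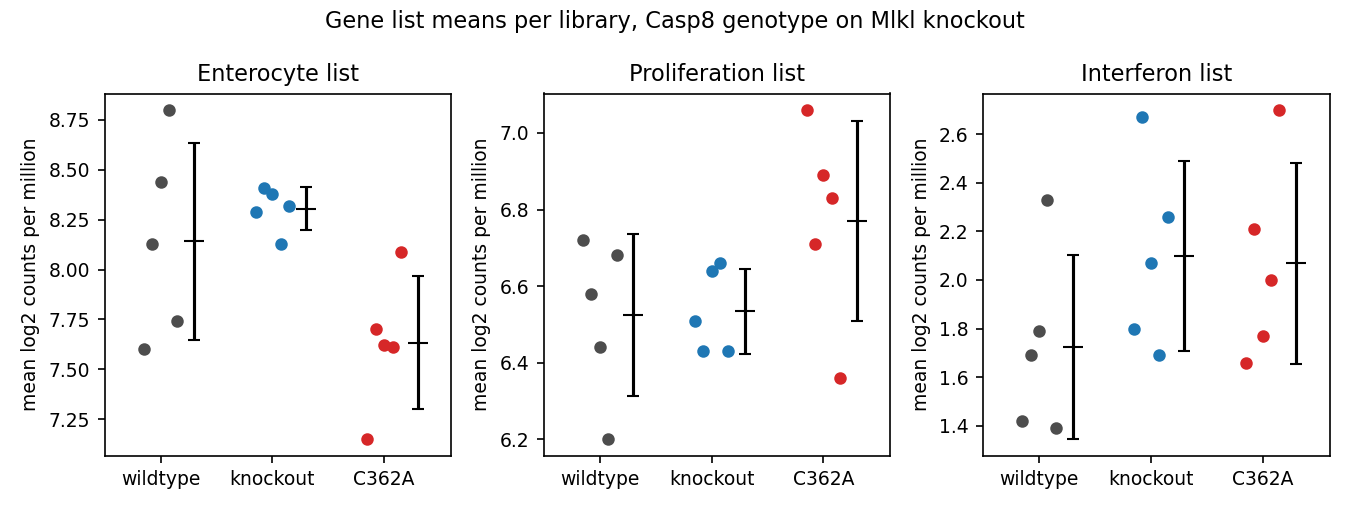
Mean log2 CPM of the members of the enterocyte, proliferation and interferon-stimulated lists in each of the 15 libraries (points, axes not starting at 0), by genotype, with bars for mean ± SD (n = 5 per group). The enterocyte list averages 7.63 ± 0.34 in C362A, 8.31 ± 0.11 in knockout and 8.14 ± 0.49 in wildtype.

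The comparison of knockout with wildtype asks what absence of caspase-8 does on the same Mlkl-deficient background. Fewer genes were called, and several were among those called in C362A. Cxcl10 was at 2 ± 0.55 against 0.734 ± 0.125 CPM (log2 fold change 1.45, SE 0.20, n = 5 each), Mmp9 at 31.6 ± 4.55 against 15.8 ± 3.50 CPM (1, SE 0.16), and Clec4n at 3.75 ± 0.556 against 2.09 ± 0.275 CPM (0.84, SE 0.14). Ccn1, a matricellular protein gene, rose to 37.1 ± 3.62 from 26.0 ± 2.41 CPM (0.51, SE 0.08, chr3:145646971-145649985). Ddit4, whose product restrains mTORC1 under stress, fell to 36.0 ± 1.26 from 49.9 ± 4.39 CPM (−0.47, SE 0.07, chr10:59949675-59951770).

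In all, 7 genes passed, 5 higher and 2 lower, with Casp8 among the lower ones. The adjusted p-values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.0143 for Cxcl10, 0.0276 for Mmp9 and Ddit4, and 0.0308 for Ccn1 and Clec4n. Slamf8, chosen after its values were seen, had 1.61 (SE 0.23, edgeR adjusted p = 0.0144). Each of the 7 separated 5 of 5 knockout libraries from every wildtype library. Chance gives this separation, in either direction, to 0.794% of unselected genes. The 7 were called from these same libraries, so it adds no support. At an unadjusted p under 0.05, 221 genes were higher and 226 lower. DESeq2 called 13 genes, while edgeR called 1 with only the 2 groups in the fit, 1 with the erythroid covariate, 2 with the filter of at least 5 CPM and 3 each with the Y-linked covariate and, chosen after seeing the data, with a Muc6 and Tff2 covariate.

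Apart from Casp8, each call was lost in at least 1 fit without a library. Cxcl10 was lost without wildtype replicate 3 (edgeR adjusted p = 0.0564), and Slamf8 without wildtype replicates 1 or 3 or knockout replicate 5 (up to 0.0723). Mmp9 was lost without C362A replicate 2, wildtype replicates 1, 3 or 5, or knockout replicates 1, 2, 3 or 5 (up to 0.107 by edgeR), and Ddit4 without C362A replicates 2 or 3, wildtype replicates 1, 3 or 4, or knockout replicates 1, 2, 3 or 5 (up to 0.134). Clec4n passed only without C362A replicates 1 or 5 or knockout replicate 1 (up to 0.147 by edgeR elsewhere), and Ccn1 only without C362A replicates 1 or 5, wildtype replicate 5 or knockout replicate 3 (up to 0.147 elsewhere). The count fell to 1 without wildtype replicate 3, to 2 without wildtype replicate 1 or knockout replicate 5, to 3 without C362A replicate 2 or knockout replicate 2, and to 4 without any of knockout replicates 1 and 3, C362A replicate 3 and wildtype replicate 4.

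Camera called 11 of 31 lists in knockout against wildtype, 9 higher and 2 lower (19 without wildtype replicate 4), of which 0 passed with an estimated correlation and 0 by fry. The interferon-stimulated list was higher, with a median of 0.35 and 30 of 31 members positive (camera adjusted p = 1.71e-09, and adjusted p = 0.501 with an estimated correlation). Ifi44 (1.55, SE 0.48), Rsad2 (1.17, SE 0.41) and Ifit3b (1.36, SE 0.51), genes induced by type I interferon, had an adjusted p of 1 in edgeR. None of the 31 passed, 0 adjusted over the list alone and 0 by DESeq2 or limma-voom, with 4 higher at an unadjusted p under 0.05. The NF-kB and cytokine list had a median of 0.08 and 19 of 25 positive (camera adjusted p = 0.000672, and adjusted p = 0.325 with an estimated correlation), with 1 member, Cxcl10, past the test over all genes and 1 adjusted over the list alone. Tnfaip2 (0.46) and Vcam1 (0.35) did not pass (edgeR adjusted p = 1). The neutrophil list had 0.57 and 14 of 15 positive (camera adjusted p = 4.97e-05, and adjusted p = 0.548 with an estimated correlation), with Mmp9 as its 1 called member over all genes and adjusted over the list alone.

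Enteroendocrine and goblet cell markers were lower in knockout. Enteroendocrine genes had a median of −0.29 and 18 of 20 negative (camera adjusted p = 2.7e-06, and adjusted p = 0.342 with an estimated correlation). The hormone genes Gcg (−0.36) and Cck (−0.44) and the serotonin synthesis gene Tph1 (−0.67), chosen after their values were seen, did not pass. Goblet cell genes had a median of −0.38 and 12 of 14 negative (camera adjusted p = 1.23e-05, and adjusted p = 0.501 with an estimated correlation), with Muc2, the gene of the main intestinal mucin, at −0.68 and Agr2 at −0.48. Over all genes and adjusted over the list alone 0 members of either list passed in edgeR, and 0 by DESeq2 or limma-voom, with 5 enteroendocrine and 4 goblet genes lower at an unadjusted p under 0.05.

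Markers of blood and liver were higher in knockout. All 19 erythroid genes were positive with a median of 0.59 (camera adjusted p = 2.12e-05), as were all 14 hepatocyte genes with a median of 0.70 (camera adjusted p = 3.04e-06), both at adjusted p = 0.501 with an estimated correlation. Albumin (Alb) had 1.28 (SE 0.96) and alpha-fetoprotein (Afp) 0.72 (SE 0.36). Hepatocyte list means spread widely within groups, at 4.33 ± 0.94 log2 CPM in wildtype and 5.08 ± 0.94 in knockout (n = 5 each). Of these 33 members 0 passed in edgeR over all genes, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom.

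Smaller shifts were found in 4 further lists. Smooth muscle genes had a median of 0.14 and 14 of 14 positive (camera adjusted p = 1.84e-06), and unfolded protein response genes 0.11 and 14 of 17 positive (0.000526), both at adjusted p = 0.325 with an estimated correlation. The enterocyte list had 0.05 and 18 of 25 positive (camera adjusted p = 0.00194), and the guanylate-binding and immunity-related GTPase list 0.16 and 11 of 15 positive (0.0347), both at adjusted p = 0.812 with an estimated correlation. Without wildtype replicates 1 or 5 the enterocyte list did not pass (camera adjusted p = 0.78 and 0.468), and the GTPase list did not pass without C362A replicate 5, wildtype replicates 1 or 5, or knockout replicates 2, 3 or 5 (up to 0.425). Over all genes and adjusted over the list alone 0 members of the 4 lists passed in edgeR, and 0 by DESeq2 or limma-voom. The largest number of members at an unadjusted p under 0.05 was 3 in any of them, for example Hspa5, the gene of the chaperone BiP (0.21, SE 0.10). Of the enterocyte genes, Lrp2 (0.70), Dpp4 (0.14) and Cdh17 (0.14), and of the inflammasome genes, Mefv (0.76), Aim2 (−0.27) and Nlrp3 (0.25), had edgeR adjusted p-values of 1. In 7 lists that did not pass, camera, median and mean were not of 1 sign. Higher by camera were proliferation (median −0.02), neuron and glia (−0.03), and the death receptor and stem lists (both just below 0), and lower were mast cell (0.04), hypoxia (0.01) and tuft cell (median −0.01, mean 0.03).

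The comparison of C362A with knockout sets an inactive protein against no protein, and it is also the test of whether the 2 effects against wildtype differ. Beyond Casp8, Ddit4 was the 1 gene called. It stood at 54.1 ± 4.92 CPM in C362A and 36.0 ± 1.26 CPM in knockout (log2 fold change 0.59, SE 0.07, n = 5 each, edgeR adjusted p = 0.00374), with 5 of 5 C362A libraries above every knockout library. Casp8 had 2.28 (SE 0.08, adjusted p = 2.61e-11 by edgeR). The chemokine Cxcl10 was at 4.29 ± 0.751 against 2 ± 0.55 CPM (1.10, SE 0.19) and did not pass (edgeR adjusted p = 0.11).

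So 2 genes were higher and 0 lower in edgeR's quasi-likelihood test, with 1193 higher and 1362 lower at an unadjusted p under 0.05. DESeq2 called 19 higher and 7 lower, limma-voom 3 and 0, and limma on log2(RPKM + 1) 5 and 0. Ddit4 passed in all 15 fits without a library (edgeR adjusted p 0.00232 to 0.0266). Without C362A replicate 5 the count was 805 (329 higher, 476 lower), and it was 3 without knockout replicate 3 or 4. Cxcl10 passed without C362A replicate 5 (0.0252) or knockout replicate 3 (0.0155), Mgl2 (1.10, SE 0.20, adjusted p = 0.186) passed without C362A replicate 5 (0.0383), and so did Trmt44, a tRNA methyltransferase gene (−0.39, SE 0.07, adjusted p = 0.255, and 0.0334 without it), all by edgeR. Over the fits without 1 library these adjusted p-values ran from 0.0155 to 0.432 for Cxcl10, from 0.0383 to 0.549 for Mgl2 and from 0.0334 to 0.575 for Trmt44.

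Enterocyte genes were lower in C362A than in knockout. Of 25 members 24 were negative with a median of −0.59 (camera adjusted p = 4.52e-14, and adjusted p = 0.684 with an estimated correlation). Apob, the structural protein gene of chylomicrons, was at 650 ± 255 against 1210 ± 67.7 CPM (−0.89, SE 0.25), the endocytic receptor gene Lrp2 at 26.6 ± 14.2 against 57.1 ± 16.4 CPM (−1.10, SE 0.33), and Mep1a at 185 ± 29.9 against 261 ± 12.4 CPM (−0.50, SE 0.13), each with an edgeR adjusted p of 0.317. Over all genes 0 passed in edgeR (20 lower at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom), and 18 were lower adjusted over the list alone. These 3 genes passed without C362A replicate 5 (edgeR adjusted p 0.0383 to 0.0409), and the highest value without another library was 0.575 for each. Within the runs of sample ID numbers, the list mean differed by −0.47 (2 libraries per group) and −0.81 (3 per group). Proliferation genes were higher, with a median of 0.26 and 21 of 22 positive (camera adjusted p = 1.11e-05, and adjusted p = 0.684 with an estimated correlation), such as Mcm3 (0.39) and Plk1 (0.36). None of the 22 passed in edgeR, 0 adjusted over the list alone, 0 by DESeq2 or limma-voom, and 10 were higher at an unadjusted p under 0.05. Over all genes 6 enterocyte genes were lower and 5 proliferation genes higher without C362A replicate 5, and 21 and 19 adjusted over the list alone. The enterocyte covariate, chosen after seeing the data, turned the proliferation list to lower, with a median of −0.09 and 1 of 22 positive (camera adjusted p = 8.48e-05, and adjusted p = 0.39 with an estimated correlation in that fit, in a range of 4.62e-08 to 0.892 over the alternatives).

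**Figure D4:**
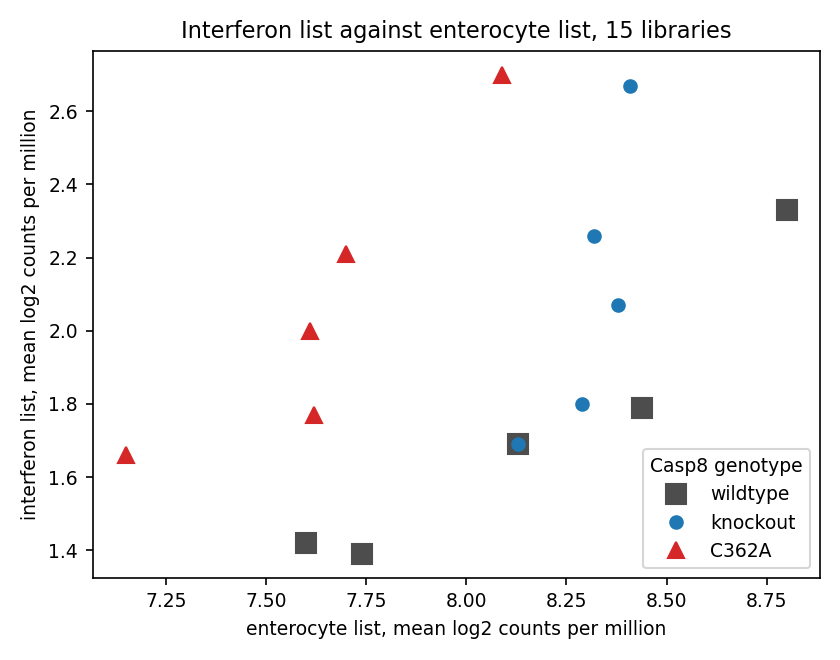
Mean log2 CPM of the interferon-stimulated list (vertical) against that of the enterocyte list (horizontal) in each of the 15 libraries, with squares for wildtype, circles for knockout and triangles for C362A, where 1 square lies under a circle. The group means of the interferon list are 1.72 in wildtype, 2.10 in knockout and 2.07 in C362A.

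The interferon-stimulated list did not pass between C362A and knockout, and its signs differed (lower by camera, median 0.04, mean −0.01). Ifit2 (0.34), Parp14 (−0.43) and Stat2 (−0.40) had edgeR adjusted p-values of 0.317, 0.404 and 0.408. With the enterocyte list mean as a covariate, an alternative chosen after seeing the data, all 31 members were positive with a median of 0.60 (camera adjusted p = 8.07e-19, and adjusted p = 0.0998 with an estimated correlation in that fit, in a range of 8.07e-19 to 1 over the alternatives). Parp14 (0.26) and Stat2 (0.22) turned positive in that fit, and 0 members passed over all genes. The enterocyte mean also differed between these groups, and the covariate does not separate the 2. The interferon list was not tested with the covariate after leaving out C362A replicate 5. The p53 list (lower by camera, mean 0.01) and the mesothelium list (higher, median 0.01, mean −0.02) did not pass either, with signs that differed.

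Of the other lists, enteroendocrine genes were higher (median 0.33, 16 of 20 positive, camera adjusted p = 0.000407, and adjusted p = 0.684 with an estimated correlation), among them Gcg (0.57) and Chgb (0.57). Fibroblast genes were higher (0.18, 18 of 20 positive, camera adjusted p = 0.00166, and adjusted p = 0.684 with an estimated correlation). Inflammasome genes were lower (−0.28, 17 of 20 negative, camera adjusted p = 0.00261, and adjusted p = 0.684 with an estimated correlation). Among them Gsdme had −0.34, Nlrc4 −0.31 and Naip1 −0.58 (62.9 ± 17.1 against 94.1 ± 6.10 CPM), each at an edgeR adjusted p of 0.317. These 3 lists passed by camera whichever library was left out. Over all genes and adjusted over the list alone 0 of their members passed in edgeR, DESeq2 or limma-voom, with 8 enteroendocrine and 6 fibroblast genes higher and 7 inflammasome genes lower at an unadjusted p under 0.05. With C362A replicate 5 left out, 3 enteroendocrine and 2 fibroblast genes were higher and 2 inflammasome genes lower over all genes, and 5, 5 and 9 adjusted over the list alone. With the enterocyte covariate, chosen after seeing the data, neither the inflammasome list (median 0.12, 14 of 20 positive, camera adjusted p = 0.0543, in a range of 9.07e-05 to 0.684 over the alternatives) nor the fibroblast list (median −0.01, 9 of 20 positive, 0.784, in a range of 0.000377 to 0.946) passed, and both medians turned sign, while the enteroendocrine list kept a median of 0.30.

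Camera called 13 of 31 lists in all, 8 higher and 5 lower (7 without C362A replicate 3 and 6 without C362A replicate 5), of which 0 passed by fry. The remaining 8 lists were each lost in some fits without a library, and all had adjusted p = 0.684 with an estimated correlation. Mast cell genes were higher (median 0.67, camera adjusted p = 0.0114), but not without C362A replicates 3 or 4 or knockout replicates 1 or 4 (up to 0.0891). Hypoxia genes were higher (0.12, 0.0434), but not without C362A replicate 5 or knockout replicates 1, 3 or 5 (up to 0.8). NF-kB genes were higher (0.08, 0.0435), but not without C362A replicates 2, 3 or 5 or knockout replicates 1, 4 or 5 (up to 0.147). Stem cell genes were higher (0.10, 0.0459), but not without C362A replicates 2 to 5, wildtype replicate 3 or knockout replicates 1 to 3 (up to 0.126). Macrophage genes were higher (0.11, 0.0459), but not without C362A replicates 3 to 5, wildtype replicates 1, 3 or 4, or knockout replicates 1 or 4 (up to 0.302). Hepatocyte genes were lower (−0.77, 0.00912), but not without C362A replicate 5 or knockout replicate 3 (0.181 and 0.117). Pancreas genes were lower (−0.92, 0.0435), but not without C362A replicates 1, 2, 3 or 5, wildtype replicates 3 or 4, or knockout replicates 2, 4 or 5 (up to 0.404). Erythroid genes were lower (−0.42, 0.0459), but not without C362A replicates 3 or 5, wildtype replicates 1, 3 or 4, or knockout replicates 3 or 4 (up to 0.8). Adjusted over the list alone Mcpt4 (1.54), Hk2 (0.46), Ankrd37 (0.73), Cxcl10, Nfkbia (0.38) and Cd44 (0.31) passed among them. Over all genes 0 members of the 8 lists passed in edgeR, while DESeq2 and limma-voom each called 1, in the NF-kB list. The fit without C362A replicate 5 had 3 NF-kB genes, 1 mast cell gene and 1 stem cell gene higher and 1 NF-kB gene lower over all genes. The largest numbers at an unadjusted p under 0.05 were 7 higher in the NF-kB list and 4 lower in each of the pancreas and hepatocyte lists.

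**Figure D5:**
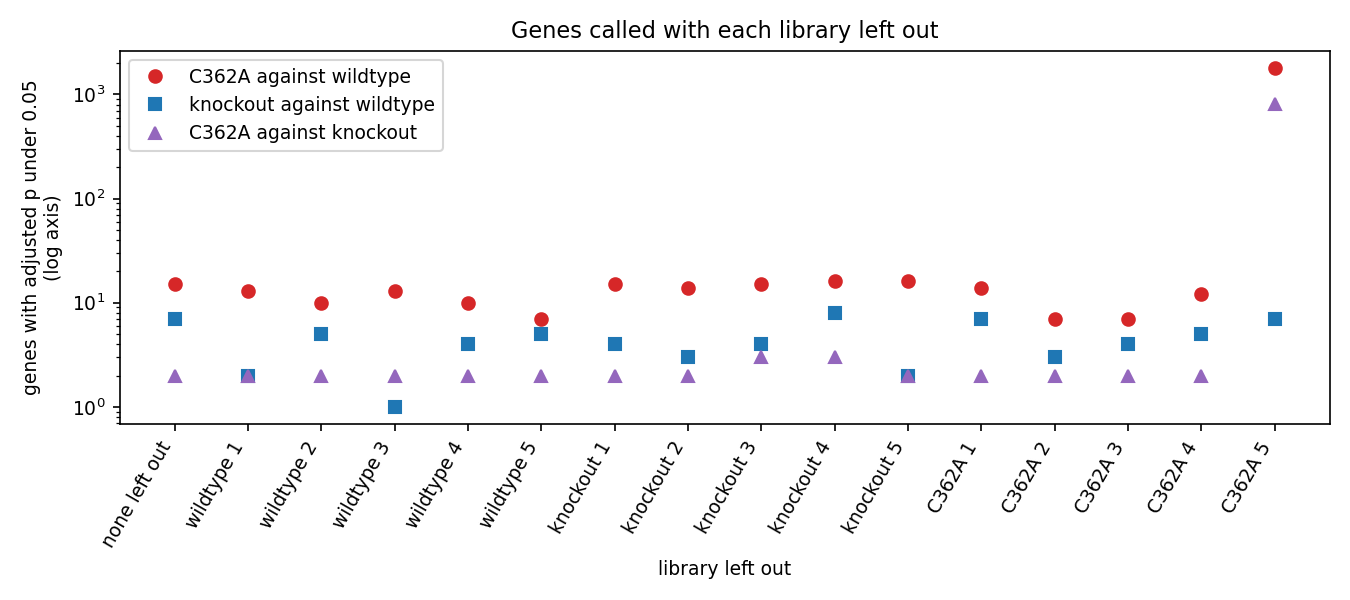
Number of genes called by edgeR's quasi-likelihood test in each comparison when each of the 15 libraries was left out in turn (logarithmic axis), beside the number with all libraries. Without C362A replicate 5 the numbers are 1807 for C362A against wildtype and 805 for C362A against knockout.

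The C362A and knockout effects against wildtype shared the same direction in 62.3% of 18370 genes and had a correlation of 0.40 across genes, which are not independent replicates. The shared wildtype libraries alone gave 66.7% and a correlation of 0.502 in 30 simulated draws with no effect (0.456 to 0.556). The covariance was 0.0299 against 0.028 in the simulated draws, a difference of 0.0019. With disjoint wildtype libraries the median correlation was 0.146 over 20 splits (−0.281 to 0.281). Called in both comparisons were Cxcl10, Slamf8, Mmp9 and Clec4n, all higher. Independent lists of these sizes would share 0.00408 genes, a value that ignores the shared wildtype libraries, and the simulated draws, in which unchanged groups leave almost no calls to share, shared at most 0. In the downward direction 0 were shared and independent lists would share 0, as C362A had 0 lower calls. These values set no scale for the overlap. The overlap of 4 fell to 0 without wildtype replicate 3, to 1 without wildtype replicate 1 or knockout replicate 5, to 2 without C362A replicate 2, wildtype replicate 5 or knockout replicates 2 or 3, and to 0 with the filter of at least 5 CPM. In the direct test between both genotypes edgeR did not call any of the 15 genes called in C362A, while DESeq2 called 3, Cxcl10 (adjusted p = 0.000288), Mgl2 (0.00476) and Serpina3g (0.0333), and limma-voom called Cxcl10 (0.0385).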

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

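Of the tests in this part, those of gut region, of Muc6 and Tff2, of macrophages of every kind, of the spread of maturity, of the label of C362A replicate 5, of the runs of sample ID numbers and of Casp1 with the enterocyte covariate were chosen after the results were seen, while those of embryo sex and of the splits of the samples were not.

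In C362A 15 genes were higher and 0 lower than in wildtype (edgeR), with a median log2 fold change of 1.5. Unlike posterior gut content, unlike content of tissue with Muc6 and Tff2, and embryo sex are argued against only weakly as its whole cause. The median was 1.56 with posterior Hox expression as a covariate and 1.56 with Y-linked expression. It was 1.45 with the mean of Muc6 and Tff2, which were high in 3 wildtype and no C362A libraries. The 15 genes were selected for differing between these same groups, which favours a median that stays high. A gain of macrophages of every kind was not decided. The upper quartile of the 22 macrophage and monocyte genes was 0.30, and the median of the called genes outside that list was 1.58. The called genes were selected for their change in this same comparison, so such a gap could be found with or without that gain. Chance was not excluded for the number of genes: 5 of 100 splits of the 10 libraries, the real one included, called at least 15 genes, the highest other split called 4238 and 94 called 0. An effect of genotype on some of the cells may account for the pattern, and the structure among the samples that those splits show stays open.

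The enterocyte list mean of C362A differed from that of knockout by −0.67 log2 units. The 3 libraries that lack posterior Hox expression or hold squamous genes do not carry it alone, since the difference was −0.55 (SE 0.15) without them. Each genotype had 2 libraries in the run of 6 sample ID numbers and 3 in the run of 9. A batch shift common to all libraries of a run therefore cancels between genotypes and cannot be the cause. The difference was −0.47 within the run of 6 and −0.81 within the run of 9. A wrong label on C362A replicate 5, whose enterocyte mean was 8.09 against 7.15 to 7.70 in the other C362A libraries, is argued against by 6 genes chosen without it, which averaged 2.42 log2 CPM there, 2.27 to 2.52 in the other C362A libraries, 1.59 to 1.98 in knockout and 0.48 to 0.96 in wildtype. The spread of gut maturity between embryos unrelated to genotype was not decided. All 5 C362A means lay below all 5 knockout means (exact permutation p = 0.00794, over 252 arrangements). Adjusted over the 31 lists, from which this one was picked, the p was 0.246. As 0.00794 is the smallest p that these arrangements allow, 1 list alone could not pass after that adjustment. A delay of the epithelium in C362A, a biological explanation that the design offers, could not be separated from that spread.

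Casp1, chosen after its values were seen, encodes the inflammasome protease and had a log2 fold change of −0.98 in C362A against knockout (SE 0.42, edgeR adjusted p = 0.334). Over the 15 libraries its log2 CPM followed the enterocyte list mean, with a Pearson r of 0.98 and a Spearman rho of 0.93, both at a permutation p of 1e-05, the smallest that 100000 resamples can give. This was the 1 relation computed, and r was 0.96 without C362A replicate 1 and wildtype replicate 4, the samples farthest from the median, and 0.98 within groups. The permutation p does not count the choice of Casp1 after its values were seen. Other genes were not set beside it, so whether Casp1 follows the enterocyte mean more closely than they do is not known. With the enterocyte mean as a covariate the fold change was 0.23 (SE 0.13, edgeR adjusted p = 0.998), between 1 and 2 standard errors from 0, so the test did not decide whether enterocyte content may be the whole source of the difference. A genotype effect on Casp1 itself stays open as well, because the enterocyte means of the C362A and knockout libraries did not overlap.

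For knockout against wildtype, 1 of 100 splits, the real one, called as many as 7 genes, and the highest other split called 1. Without Casp8, which is deleted in the knockout, the real split called 6 and the highest other split 1. This argues against chance for that number at the level set beforehand, but 100 splits cannot exclude it. The number itself fell to 1 without wildtype replicate 3. For C362A against knockout, 3 of 100 splits called at least 2 genes, which is also under that level. However, Casp8, deleted in 1 of the groups, is 1 of the 2. Without Casp8, 4 of 100 splits called at least 1 gene, the highest other split called 1735 genes and 96 called 0 with it. A split that calls so many genes points to a structure of the samples that genotype does not describe.

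The direct test between C362A and knockout found different effects of the 2 genotypes on Casp8 (2.28) and on Ddit4 (0.59), both by edgeR. In 8 of 243 groups of 5 libraries 1 library lay far from the rest by Dixon's test, where chance gives about 12. Ccl12 and the gene with ID 102641905, which has the same counts, were at −0.30 log2 CPM in C362A replicate 4 and at 0.33 to 0.40 in the other C362A libraries. The hypoxia and glycolysis list mean was 7.23 in C362A replicate 5, against 6.62 to 6.75 in the others of its group, and 6.82 in knockout replicate 4, against 6.59 to 6.64. Apobec3 was at 3.09 log2 CPM in knockout replicate 4, with 3.50 to 3.63 in the other knockout libraries. The inflammasome list mean was 3.55 in that same library, with 3.95 to 4.11 in the others. Knockout replicate 5 was highest in the fibroblast list mean (7.60, others 7.25 to 7.33) and in the mesothelium list mean (4.65, others 4.16 to 4.26).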

How the results depend on the processing

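The covariates for enterocyte, posterior Hox, and Muc6 and Tff2 expression, the estimated correlation in the enterocyte fit, the surrogate variables, limma on log2(RPKM + 1), the fit without 3 libraries of unlike Hox or squamous expression, and the rule for sign changes given last were chosen after the data were seen, and all other alternatives before. Across settings other than single left-out libraries, called genes passed in the same direction in 344 of 420 values and were lost in 76, and called lists passed in 485 of 666, were lost in 160 and turned sign in 21. Without single libraries, 263 of 360 gene values and 481 of 555 list values were kept, 97 and 74 were lost, and no called gene or list turned sign. Mmp9 (adjusted p 2.04e-10 to 0.017), Clec4n (1.33e-08 to 0.0281) and Cxcl10 (3.6e-25 to 0.000496) passed in C362A against wildtype in every setting that tested them, as did Slamf8, Mgl2 and Spic, while Serpina3f was lost in 1 (0.0574). No paired analysis was possible because the labels carry no replicate numbers, and those used here follow accession order. The alternatives for files without counts were not run, since counts were present. Depth limits the genes under 1 CPM, and a filter of 5 CPM left 9 of 15 and 3 of 7 genes called against wildtype untested.

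Against 15, 7 and 2 genes in C362A against wildtype, knockout against wildtype and C362A against knockout, DESeq2 called 54, 13 and 26. The 5 CPM filter left 1 and 2 in the first and second comparisons, where 5 (adjusted p 0.0938 to 0.119) and 2 (0.0501 and 0.0527) of the genes it still tested were lost, with a correlation of the 2 effects of 0.30 and an overlap of 0. Fits of only the groups compared, with fewer samples, called 1 gene in knockout against wildtype and 4 genes and 8 lists in C362A against knockout. The Y-linked covariate gave 7 and 3 genes against wildtype and 7 lists in C362A against knockout, the erythroid covariate 1 gene in knockout, the enterocyte covariate 9 genes in C362A against wildtype, the Muc6 and Tff2 covariate 3 genes and 17 lists in knockout against wildtype, the Hox covariate 8 lists in C362A against knockout, and limma on log2(RPKM + 1) 5 genes there. For these counts the cause was not tested. By their construction, adjusted p under 0.01 left 7 and 1 genes against wildtype, and an absolute log2 fold change of at least 1 left 4 in knockout against wildtype and 1 in C362A against knockout. List counts of 13, 11 and 13 became 0, 0 and 0 with an estimated correlation, 2, 0 and 1 with it in the enterocyte fit, and 1, 0 and 0 by fry. The correlation of the 2 effects, 0.40, was 0.15 with disjoint wildtype libraries, which removes the shared controls.

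Without single libraries, gene counts ran from 7 to 1807, 1 to 8 and 2 to 805, list counts from 10 to 15, 10 to 19 and 6 to 14, the correlation from 0.32 to 0.52 and the overlap from 0 to 4. The count of 1807 and that of 805 belong to the fit without C362A replicate 5, which had the highest hypoxia list mean and an enterocyte mean unlike its group; the cause was not tested.

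Some results turned sign, for lists in camera's direction, given here with the median, and the cause was not tested except where a list served as its own covariate. The median itself did not turn for proliferation and erythroid genes in knockout against wildtype, for interferon genes in C362A against knockout, or at the 0.01 for proliferation. With the erythroid covariate, knockout against wildtype had −0.12 for proliferation and 0.23 for the erythroid list, with camera lower for both. Without wildtype replicate 4 proliferation had −0.09 there. With the enterocyte covariate, C362A against wildtype had 0.05 for inflammasome, 0.04 for death receptor, 0.03 for enterocyte and −0.01 for proliferation genes, and knockout against wildtype −0.02 for enterocyte genes. In the same setting C362A against knockout had 0.26 for Parp14, 0.22 for Stat2, 0.60 for interferon, 0.12 for inflammasome, 0.07 for death receptor, 0.05 for enterocyte, −0.07 for stem, −0.09 for proliferation (called lower) and −0.01 for fibroblast genes. With an estimated correlation in that fit the same lists turned. Of these, interferon (higher by camera, adjusted p = 0.0998) was not counted, under the rule given last in this paragraph. With 2 surrogate variables, C362A against wildtype had −0.03 for proliferation and −0.45 for erythroid genes, and C362A against knockout 0.38 for interferon, 0.01 for proliferation and −0.02 for smooth muscle genes. A further 224 sign changes, of at most 0.63, were of results past the threshold in neither fit. They were within 1 standard error of 0 in at least 1 of the fits compared, but not always in both. For this an unadjusted p of at least 0.32 was used, from the list test for lists. They were counted as unchanged because no direction had been given.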

Other observations

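The test of interferon-stimulated genes with the enterocyte list mean as a covariate, the estimated correlation in that fit, the gut region genes and the values of C362A replicate 5 were chosen after the data were seen. Interferon-stimulated and enterocyte genes were set in 1 model because their list means both varied widely among libraries of 1 genotype. With the enterocyte mean as a covariate, all 31 interferon-stimulated genes were positive in C362A against wildtype, with a median of 0.85 in place of 0.34 (camera adjusted p = 1.21e-35 at the preset correlation of 0.01, in a range of 1.21e-35 to 0.632 over the alternatives). The estimated correlation was 0.371 in that fit (adjusted p = 0.0239) and 0.561 without the covariate (adjusted p = 0.632), where the list also did not pass without C362A replicate 5 (camera adjusted p = 0.102). Adjusted over the list alone 26 passed, among them the antiviral gene Ifit3 (1.74, SE 0.35) and Isg15 (1.51, SE 0.32), but over all genes 0 passed in edgeR (lowest adjusted p 0.0955, for Oasl1). Against knockout all 31 were positive with a median of 0.60 (8.07e-19 by camera, 0.0998 with an estimated correlation, in a range of 8.07e-19 to 1), 14 of them past the test adjusted over the list alone. In knockout against wildtype 27 of 31 were positive with a median of 0.18 (0.000191, 0.676 with an estimated correlation, in a range of 4.42e-21 to 0.694). In that setting the guanylate-binding and immunity-related GTPase list had a median of 0.53 and the MHC class I list 0.24 in C362A against wildtype (camera adjusted p = 8.86e-11 and 1.18e-09, both 0.0626 with an estimated correlation, in ranges of 8.86e-11 to 0.632 and 1.18e-09 to 0.898). The rise was not particular to such genes. In that fit NF-kB had a median of 0.30 (camera adjusted p = 9.63e-11, 0.00336 with an estimated correlation). Macrophage genes had 0.28 (6.05e-09, 0.148) and neutrophil genes 1.49 (7.02e-08, 0.305). The inflammasome (0.05), proliferation (−0.01) and mesothelium (−0.12) lists did not pass by camera. Against knockout NF-kB also passed with an estimated correlation (0.0411). A candidate explanation is that the C362A genotype raises interferon-stimulated genes at a given epithelial content. However, the covariate may itself be changed by genotype, and no interferon-stimulated gene passed over all genes. C362A replicate 5 had the highest interferon list mean of all libraries (2.70) and the highest enterocyte mean of its group (8.09). The list was not tested with the covariate after leaving that library out, so how far the result rests on it is not known.

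Genes of gut region set some libraries of each genotype apart. The posterior Hox genes averaged −3.37 log2 CPM in C362A replicate 1 and −3.43 in knockout replicate 4, and 0.59 to 2.17 in the other 13 libraries. Hoxd10 was at 0.0311 and 0 CPM in those libraries and at 1.04 to 11 CPM elsewhere, and Hoxd13 was at 0 in both. C362A replicate 4 held some squamous epithelium genes, with Krt13 at 53.1 CPM, Krt15 at 82.0 CPM and Krt5 at 27.3 CPM, where the other 14 libraries had at most 0.899, 4.69 and 0.677 CPM. Krt4 (79.3 CPM, at most 0.811 elsewhere) and Krt6a (3.68, at most 1.27) were also highest there, but Krt14 (2.55 CPM, 1.39 to 5.93 elsewhere) and Dsc3 (0.724 CPM, 0.12 to 3.59 elsewhere) were not. Of the stomach genes, Muc6 and Tff2 were high in wildtype replicates 2, 3 and 4 and knockout replicate 2 (Muc6 1.7 to 3.09 CPM, at most 0.289 elsewhere, and Tff2 1.86 to 6.47 CPM, at most 1.03 elsewhere), while Barx1, Cldn18 and Tff1 did not separate these libraries. The labels name the small intestine as primary tissue and the intestine as source, and do not give the length of gut in each sample.

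C362A replicate 5 differed from the rest of its group on the first principal component, which held 32.3% of the variance. It scored 30.34 against −8.19 to −55.56 in its group, but lay within the wildtype and knockout libraries (−16.29 to 42.56). It had the highest interferon list mean of the 15 libraries (2.70) and the highest hypoxia and glycolysis mean (7.23, against 6.53 to 6.90 in the other 14). Vegfa, an angiogenic factor gene, was at 211 CPM there and at 73.3 to 175 CPM elsewhere. The glucose transporter gene Slc2a1 was at 279 CPM (142 to 220 elsewhere), and the carbonic anhydrase gene Car9 at 25.5 CPM (12.3 to 20.9 elsewhere). Ldha, a lactate dehydrogenase gene of the same list, was at 1000 CPM, within the 698 to 1080 CPM of the others. Without this library 590 genes were called in C362A against both other genotypes in the same direction, 223 higher and 367 lower. Both comparisons use the same remaining C362A libraries, which alone raises such an overlap, and no scale for it was computed. Splits that ignored genotype also called many genes, up to 4238 among the C362A and wildtype libraries. The 590 are therefore no measure of how many genes the C362A genotype changed.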
